A study of Mus musculus with 14 samples.

How the data were processed

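RNA sequencing was read from retinal ganglion cell samples of female mice aged 7 to 8 weeks with experimental autoimmune encephalomyelitis (EAE, an immune attack on myelin used as a model of multiple sclerosis) and from untreated (naive) mice. Per the labels, the samples came before symptoms (called pre here), at symptom onset and at the peak of disease, and total RNA was extracted with a miRNeasy kit. The labels describe no sort or gate for the cells. The authors deposited 1 table of raw read counts per gene symbol, written by HTSeq, with 40840 genes and 5 summary lines for 13 libraries. The processing notes name cutadapt, HISAT2, HTSeq and DESeq2, but the genome build, annotation and strand setting were not given in the sources used here, so genes are named by symbol and no coordinates are given. Of the symbols, 39350 (96.4%) were found in the RefSeq gene table of mouse assembly GRCm38.p6, and exon lengths came from GENCODE M21. The labels list 14 samples, 2 of them at the peak, and 1 peak sample was not analysed here. The libraries were 4 naive, 4 pre, 4 onset and 1 peak.

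Gene totals ran from 2596705 to 7641214 counts per library. The smallest number of counts told apart from 0 was taken as 3, which equals 0.377 to 1.14 CPM (the usual count scaling to a common library total) in a single library. Folds against a group with 0 counts were computed against 3 counts over the whole group. These floors, and all counting intervals, cover counting error only, since reads without molecular identifiers are not independent molecules.

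Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr by group with a minimum count of 10, 1 quasi-likelihood fit with robust dispersion over all 13 libraries, and a two-sided F test per comparison. That left 14893 genes. Adjusted p is Benjamini-Hochberg over those genes, with a threshold of 0.05. The lone peak library was assumed to vary like the other groups. Log2 fold changes come with the standard error (SE) from the fit, and CPM values with the standard deviation (SD) over the libraries of a group. Each EAE stage was compared with naive, and each stage with the one before it, which is also the test of whether 2 stages differ in their change from naive.

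A total of 40 gene lists, 17 of cell type markers and 23 of gene groups, were written before the data were examined, as were the test, the rule for naming genes and the alternatives, except where the closing section says otherwise. Lists with at least 3 tested members (38) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, two-sided and adjusted over the lists of a comparison. Because members of a marker list vary together, each list was also tested with an estimated correlation, with fry, and with an exact permutation of the mean log2 CPM of its members where both groups had 4 libraries. The count of members past the threshold is given over all genes and adjusted over the list alone. Some genes stand in several lists, so these lists are not separate lines of evidence. C1qa, C1qb and C1qc are in the microglia and the complement list, and Itgam in the complement and the monocyte and neutrophil list. Nefl, Nefm and Nefh are in the ganglion cell and the axonal list.

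Named genes follow 1 rule. Per comparison with naive they are the 8 highest and 8 lowest log2 fold changes among genes past the threshold with a mean of at least 1 CPM in the higher group and no overlap between groups. For each list past its test, up to 4 members with the smallest p are added, and Rbpms, Slc17a6, Pou4f1, Pou4f2, Thy1, Sncg and Nefl are always given. For successive stages it is 4 each way, and where fewer than 5 genes pass, 5 each way with the smallest p are named as not passing. Gene models without a proper symbol were skipped, and some genes that met the rule are not reported here. Genes outside the rule are marked as chosen after their values were seen.

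The rod index is the mean log2 CPM of the rod photoreceptor markers of a library. Correlations over the 13 libraries have two-sided permutation p-values from 100000 resamples, adjusted over 5 relations. The alternatives were DESeq2 1.42.0, limma-voom with quality weights, other scaling factors and filters, only the 2 groups compared, the replicate number as a block, the rod index as a covariate, and leaving out each library in turn. Removal of each library's trend over exon length (lowess, span 0.3) and fits without the 4 libraries with the highest rod index or without the peak library were added after the data had been seen. The pipeline was checked on simulated data. Counts were drawn gene by gene from the mean and dispersion of each gene in the real libraries, with 200 genes changed. Of those changed 2-fold the edgeR test found 56.7% in pre against naive, 50.7% in onset against naive and 34.3% in peak against naive. Of those changed 1.5-fold it found 16.4%, 22.4% and 1.49%. Variation that genes share, such as rod content, was not simulated, so detection in the real libraries may differ. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.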

Results

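Gene expression was measured in 13 libraries of retinal ganglion cell RNA from mice at successive stages of EAE: 4 naive, 4 pre (before symptoms), 4 at symptom onset and 1 at the peak of disease. Gene totals ran from 3308627 to 6590972 counts in the naive libraries, from 2910710 to 6168741 in pre and from 2596705 to 6413329 at onset. The peak library held 7641214. Reads outside any annotated gene made up 22.8% to 27.6% of the reads counted, and replicates of a group correlated across genes at r = 0.935 to 0.984, where genes are not independent replicates. Replicate variation over the genes was moderate, with a common biological coefficient of variation of 0.220. The labels do not say whether replicates are separate animals, so p-values that rest on replicates measure only the spread between these samples. The camera p-values of gene lists at the preset correlation compare members with other genes and take members as nearly independent. They do not show that a list shift exceeds the spread between samples. Exact permutation of list means called 0 of 38 lists in pre against naive, onset against naive and onset against pre. With 4 libraries against 4 it cannot give a p below 0.0286, so its adjusted values say little. The peak stage has 1 library, so no SD is given for it.

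Every library held ganglion cell transcripts together with abundant transcripts of other retinal cells. The ganglion cell markers averaged 4.87 ± 0.741 log2 CPM in naive (SD, n = 4), 5.34 ± 0.729 in pre, 4.15 ± 0.510 at onset and 3.53 in the peak library. The amacrine cell markers, which belong to inhibitory interneurons of the inner retina, were higher throughout, at 7.20 ± 0.239, 7.49 ± 0.175, 7.38 ± 0.254 and 7.17. The rod photoreceptor markers averaged 6.02 ± 2.14 in naive and 5.38 ± 1.22, 6.05 ± 1.46 and 6.50 in the later stages, and ran from 3.79 to 8.11 within naive alone. Markers of microglia and macrophages, the resident immune cells, averaged 3.66 ± 1.19 in naive, 5.23 ± 0.697 in pre, 4.91 ± 1.10 at onset and 5.51 at the peak.

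**Figure D1:**
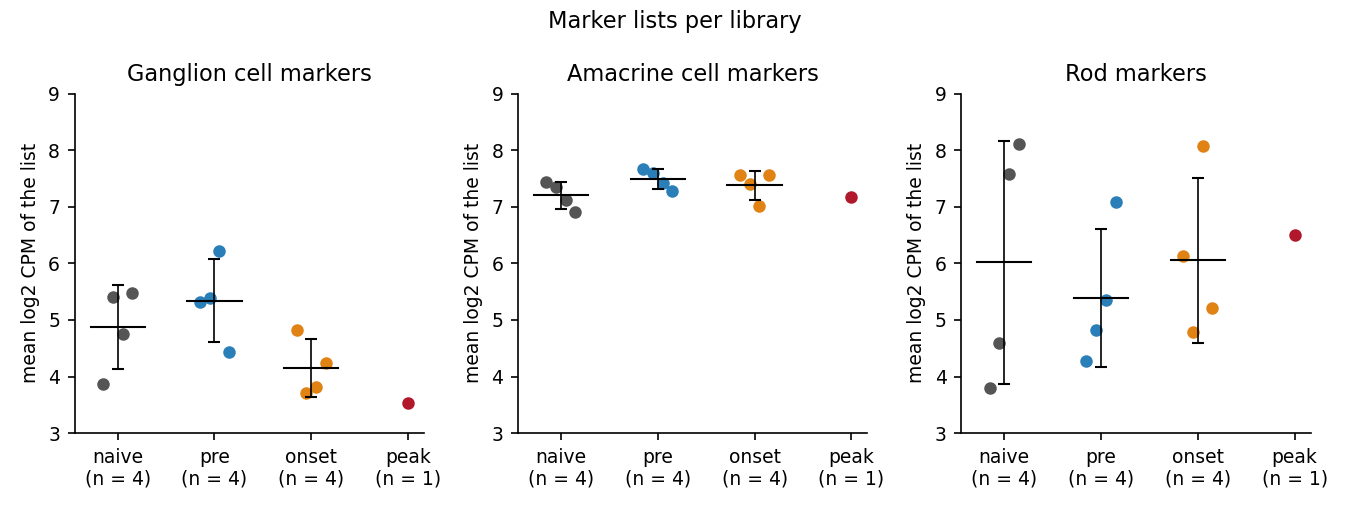
Mean log2 CPM of the ganglion cell, amacrine cell and rod photoreceptor markers in each of the 13 libraries, by stage, with the group mean and SD. Rod markers ran from 3.79 to 8.11 within the naive group, while amacrine markers stayed near 7.20 in naive and 7.17 in the peak library.

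The rod content of a library was its main axis of variation. The rod index tracked the first principal component, which held 28.5% of the variance (Pearson r = 0.966, Spearman rho = 0.940, permutation p = 1e-05 and adjusted p = 5e-05 for both). That p is the smallest that 100000 resamples can give, and r was 0.940 without the 2 libraries farthest from the median. Microglial markers rose with it (r = 0.662, permutation p = 0.0132, adjusted p = 0.0166). Their rho was 0.709 (permutation p = 0.00848, adjusted p = 0.0106), and r was 0.615 without those 2 and 0.945 once the group means were removed. Bipolar cell markers also rose with it (r = 0.869, permutation p = 0.00018, adjusted p = 0.00045; rho = 0.830, adjusted p = 0.00185; r = 0.820 without those 2). Amacrine markers fell with it (r = -0.825, permutation p = 0.00073, adjusted p = 0.00122; rho = -0.758, adjusted p = 0.00638; r = -0.672 without those 2). Ganglion cell markers showed no relation to it (r = -0.100, permutation p = 0.742; rho = -0.00549, permutation p = 0.992). These 5 relations are all that were computed, over the 13 libraries, and no batch is given in the labels.

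**Figure D2:**
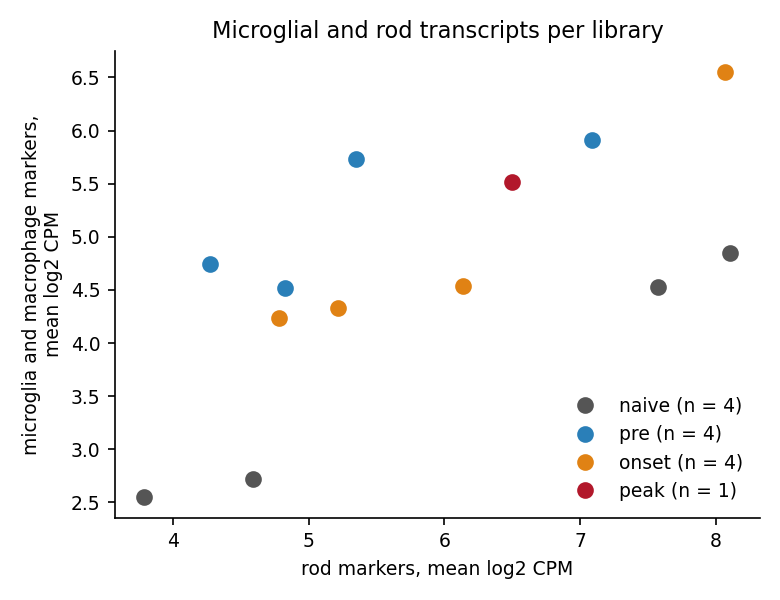
Mean log2 CPM of the microglia and macrophage markers against that of the rod markers, 1 point per library, coloured by stage. At a like rod level the naive libraries sit below the EAE libraries, and within stages both rise together (r = 0.945 with group means removed).

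Before symptoms, the question was which transcripts change ahead of any clinical sign. Tlcd4 had the smallest p, followed by the neutrophil genes S100a9 and Retnlg, and none of them passed over all genes. S100a9 and S100a8, the subunits of the inflammatory protein calprotectin, had 0 counts in all 4 naive libraries and reached 13.5 ± 5.81 CPM and 5.45 ± 3.36 CPM in pre (SD, n = 4), at least 79.8-fold and 32.3-fold higher. Retnlg, a resistin-like gene of neutrophils, was at least 11.1-fold higher at 1.88 ± 0.886 CPM, and Ifitm1, an interferon-induced membrane protein, at least 7.84-fold higher at 1.32 ± 0.524 CPM. Cxcr2, the chemokine receptor that draws neutrophils, had 1 count in naive and 1.96 ± 0.725 CPM in pre. S100a9, S100a8, Retnlg, Ifitm1 and Cxcr2 each had an adjusted p of 0.807 over all genes in edgeR.

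Microglial transcripts had higher means before symptoms. Csf1r, the growth factor receptor on which microglia depend, averaged 196 ± 89.0 CPM in pre against 68.3 ± 54.0 in naive (SD, n = 4 each), and C1qb, a complement component made by microglia, 72.3 ± 35.3 against 22.0 ± 17.0. Aif1 (log2 fold change 1.63 ± 0.61 SE) and Tmem119 (1.41 ± 0.67) were higher too. All 16 tested microglia and macrophage markers were higher (median 1.35, adjusted p = 2.38e-12, and adjusted p = 0.555 with an estimated correlation). So were 8 of 9 monocyte and neutrophil markers, including Csf3r (1.70 ± 0.79) and Itgam (1.44 ± 0.80) (median 1.44, adjusted p = 1.02e-06, and adjusted p = 0.555 with an estimated correlation). Csf1r was at 1.49 ± 0.73 log2, so the rise of Csf3r and Itgam cannot be told apart from that of microglial transcripts. Of the 14 complement genes 11 were higher, with C5ar1 at 1.98 ± 0.80 and C3 at 1.09 ± 0.56 (median 0.93, adjusted p = 7.38e-05, and adjusted p = 0.555 with an estimated correlation). Cd59a, which blocks the final step of complement, was at -0.58 ± 0.31. No member of these 3 lists passed over all genes, and 2 of the monocyte and neutrophil list passed adjusted over the list alone. With the rod index as a covariate, 14 of the 16 microglial markers passed over all genes in pre, against 2 at onset, 7 at the peak and 0 from pre to onset. Among the 14 were C1qb (2.44 ± 0.25, adjusted p = 0.00350), Csf1r (2.28 ± 0.28, adjusted p = 0.00670) and P2ry12 (1.89 ± 0.35, adjusted p = 0.0337). With this covariate S100a9 passed in pre too (adjusted p = 0.0337), but not at onset (0.0627) or at the peak (0.0516).

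**Figure D3:**
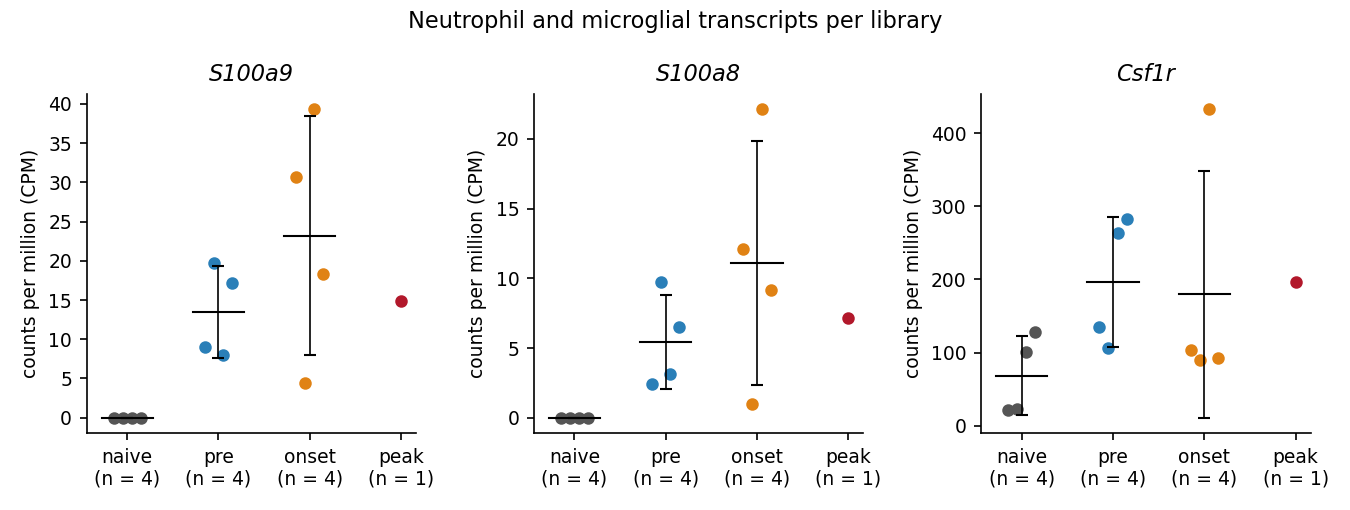
CPM of S100a9, S100a8 and Csf1r in each of the 13 libraries, with group means as lines and SDs as bars. S100a9 and S100a8 are at 0 in the 4 naive libraries and above 0 in all 9 EAE libraries, and onset library 3 has the highest Csf1r value at 433 CPM.

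Among the other lists, heat shock and glycolysis genes leaned higher before symptoms and cone genes lower. All 13 heat shock genes were higher (median 0.24, adjusted p = 1.42e-04, and adjusted p = 0.555 with an estimated correlation). Hsph1, a chaperone of the Hsp110 family, averaged 125 ± 20.2 against 82.8 ± 17.2 CPM and Hspa8 602 ± 63.4 against 511 ± 90.6 (SD, n = 4 each), and 1 member passed adjusted over the list alone. Glycolysis genes were higher in 17 of 22, with Ldha at 0.26 ± 0.10 and Gpi1 at 0.23 ± 0.09 log2 (median 0.11, adjusted p = 8.83e-04). That list had adjusted p = 0.690 with an estimated correlation, and nuclear oxidative phosphorylation genes did not pass (41 of 70 higher, median 0.0280, adjusted p = 0.168). The axonal cytoskeleton and transport list was higher in 25 of 33, led by the tubulins Tubb3 (0.36 ± 0.15) and Tuba4a (0.35 ± 0.16) (median 0.08, adjusted p = 0.00693, and adjusted p = 0.702 with an estimated correlation). Synapse genes were higher in 27 of 37, with Gria3 at 0.27 ± 0.11 and Nrxn3 at -0.17 ± 0.08 (median 0.08, adjusted p = 0.0241, and adjusted p = 0.867 with an estimated correlation). Amacrine markers were higher in 12 of 13, with Tfap2a at 0.31 ± 0.23 (median 0.17, adjusted p = 0.0183, and adjusted p = 0.792 with an estimated correlation). All 11 cone markers were lower, with Pde6c at -1.95 ± 0.97 and Opn1mw at -1.82 ± 0.92 (median -1.67, adjusted p = 0.0183, and adjusted p = 0.867 with an estimated correlation). Rod markers were lower in 15 of 15 (median -1.25), with an adjusted p of 0.162. No member of these groups passed over all genes in edgeR.

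Several of these calls depended on 1 library. The cone call ended without naive 4, naive 5 or pre 2 (adjusted p = 0.201, 0.288 and 0.157) and the amacrine call without naive 4, naive 5, pre 1 or pre 2 (0.179, 0.557, 0.109 and 0.128). The synapse call ended without naive 4, naive 5, pre 2 or pre 3 (0.0677, 0.312, 0.0886 and 0.0905), the axonal call without pre 3 (0.0571) and glycolysis without pre 4 (0.0588). Without the 4 libraries richest in rod transcripts all 6 lists ended above the threshold, with heat shock at 0.405, synapse at 0.877 and axonal at 0.140. There the cone, amacrine and glycolysis lists also changed direction (0.535, 0.785 and 0.894). With the rod index as a covariate the amacrine and synapse calls ended (0.0796 and 0.132), and with the replicate number as a block the cone, amacrine and synapse calls did (0.104, 0.0678 and 0.137).

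Ganglion cell markers did not pass in pre against naive. Rbpms, which marks all ganglion cells, averaged 32.5 ± 23.9 CPM against 13.1 ± 7.75 in naive (SD, n = 4 each), the glutamate transporter Slc17a6 32.2 ± 27.5 against 17.3 ± 13.1, and the transcription factor Pou4f1 26.5 ± 22.3 against 13.3 ± 9.20. Pou4f2 averaged 7.40 ± 7.97 against 3.49 ± 3.08. Thy1 differed by 0.25 ± 0.22 log2, Sncg by 0.16 ± 0.70 and Nefl, the light neurofilament, by -0.24 ± 0.40, each within the spread between replicates. The ganglion cell list was higher in 9 of 14 members (median 0.32, adjusted p = 0.0595). Signs turned without 1 library for Pou4f2 (-0.0149 without pre 3), Sncg (-0.20 without naive 1, -0.09 without naive 4 and -0.13 without pre 3) and Nefl (0.32 without naive 5). Other genes with the smallest p, none past the threshold, were Abcc8, a subunit of a potassium channel (29.2 ± 6.20 against 15.8 ± 1.98 CPM), Tlcd4 (-0.73 ± 0.13), Aldh6a1 (-0.42 ± 0.10), Smoc2 (-1.21 ± 0.29) and Ndor1 (-0.31 ± 0.07). Oxtr, the oxytocin receptor, had naive counts of 282, 2, 47 and 984 against 1 to 5 in pre, so its difference rested on some naive libraries.

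Across all 14893 genes, edgeR called 0 genes in pre against naive (832 at an unadjusted p below 0.05, where 744.65 are expected by chance; smallest adjusted p 0.807). DESeq2 called 6 (5 higher, among them S100a9, S100a8 and Retnlg, and Oxtr lower), limma-voom 0, and edgeR with the rod index as a covariate 99, of which 97 were higher.

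At symptom onset, the comparison asks what accompanies the first clinical signs. The neutrophil genes were again present, with S100a9 at 23.2 ± 15.2 CPM (SD, n = 4) and S100a8 at 11.1 ± 8.75, at least 137-fold and 65.7-fold above the naive floor. Retnlg was at least 17.8-fold and Ifitm1 at least 8.94-fold higher. The edgeR adjusted p was 0.402 for S100a9 and Retnlg and 0.616 for S100a8 and Ifitm1. S100a9 passed in edgeR when onset 2, the library with its lowest count, was left out, which made it the 1 gene called. Chil3, a lectin of myeloid cells, had 1 count in naive and 1.78 ± 1.20 CPM at onset, and Lyz2, lysozyme, was 1.58 ± 0.63 log2 higher. All 9 monocyte and neutrophil markers were higher (median 1.44, adjusted p = 2.97e-09, and adjusted p = 0.528 with an estimated correlation), and 3 passed adjusted over the list alone. All 16 microglial markers were higher (median 1.18, adjusted p = 7.97e-09, and adjusted p = 0.528 with an estimated correlation), with C1qb at 74.9 ± 71.6 CPM and Aif1 at 1.42 ± 0.62 log2. Complement genes were higher in 12 of 14, with C3 at 1.38 ± 0.55 and C2 at 0.95 ± 0.41 (median 1.41, adjusted p = 1.17e-04, and adjusted p = 0.528 with an estimated correlation). The microglial mean rested largely on onset 3, which had 433 CPM of Csf1r against 90.4 to 103 in the other 3 onset libraries and also the highest rod index of its group at 8.07.

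Immune signalling genes, which had not passed before symptoms, were higher at onset. Antigen presentation genes were higher in 18 of 20 (median 0.98, adjusted p = 1.53e-06, and adjusted p = 0.528 with an estimated correlation). H2-K1, a class I molecule, averaged 64.4 ± 29.6 CPM against 32.1 ± 3.72 in naive (SD, n = 4 each), and the class II gene H2-Eb1 was 2.40 ± 0.90 log2 higher. Cytokine and NF-kB genes were higher in 18 of 20 (median 0.79, adjusted p = 2.73e-05, and adjusted p = 0.528 with an estimated correlation), and 1 passed adjusted over the list alone. Among them were the chemokines Ccl12 (6.96 ± 7.89 against 0.787 ± 0.490 CPM) and Cxcl12 (18.9 ± 4.03 against 9.07 ± 3.55) and Il1b (2.87 ± 1.01 log2). Ccl12 and Il1b rested largely on onset 3, at 18.8 and 18.5 CPM. The other onset libraries had 2.27 to 3.42 and 0.970 to 3.27. Tnfaip2 had 3 counts in naive and 1.17 ± 0.636 CPM at onset. Interferon response genes were higher in 28 of 30 (median 0.46, adjusted p = 4.57e-04, and adjusted p = 0.536 with an estimated correlation). Igtp was at 1.13 ± 0.40, Trim30a at 1.73 ± 0.62 and Gbp2 at 1.44 ± 0.74 log2. Cxcl10 had 0 naive counts and 0, 0, 11 and 3 at onset, most of them in onset 3. The interferon call ended without onset 3 (adjusted p = 0.357) and without the 4 rod-rich libraries (0.714). Without onset 3, antigen presentation (0.00998), microglia (4.22e-04) and monocyte and neutrophil markers (2.28e-05) stayed past the threshold.

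Most ganglion cell and axonal genes had lower means at onset. Nefl averaged 115 ± 9.41 CPM against 325 ± 227 in naive (SD, n = 4 each; -1.50 ± 0.41 log2, adjusted p = 0.767), Nefm, the medium neurofilament, 57.7 ± 19.8 against 157 ± 71.8, and Slc17a6 5.27 ± 4.15 against 17.3 ± 13.1. Sncg was at -1.72 ± 0.78, Rbpms at -0.95 ± 0.69, Pou4f1 at -0.65 ± 0.94 and Pou4f2 at -1.81 ± 1.09, while Thy1 was at 0.31 ± 0.22. The ganglion cell list was lower in 12 of 14 members (median -1.07, adjusted p = 0.00481, and adjusted p = 0.528 with an estimated correlation; 0 passed over all genes and 2 adjusted over the list alone). That call ended without naive 2 (adjusted p = 0.0687) and without the 4 rod-rich libraries (0.0733). Voltage-gated channels were lower in 21 of 27 (median -0.14, adjusted p = 0.00539, and adjusted p = 0.528 with an estimated correlation). The sodium channel gene Scn1a averaged 135 ± 18.6 against 191 ± 45.7 CPM. Axonal genes were lower in 22 of 33, with Map1a at -0.47 ± 0.18 (median -0.07, adjusted p = 0.0129, and adjusted p = 0.528 with an estimated correlation). Synapse genes were lower in 25 of 37 (median -0.05, adjusted p = 0.0388, and adjusted p = 0.638 with an estimated correlation), and 1 passed adjusted over the list alone. The vesicle calcium sensor Syt2 averaged 1.17 ± 0.417 against 5.67 ± 3.48 CPM, and the scaffold Shank1 was at -0.31 ± 0.11 log2. The channel, axonal and synapse calls ended without onset 3 (adjusted p = 0.0863, 0.421 and 0.694) or naive 2 (0.0931, 0.0635 and 0.268). Without naive 1 the axonal and synapse calls ended (0.172 and 0.307), and without onset 1 the synapse call (0.0807). With the length trend removed they ended as well (0.0677, 0.0825 and 0.348), and the synapse call also with the rod index as a covariate (0.0584).

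Protein synthesis, breakdown and respiration genes were slightly higher at onset. Proteasome genes were higher in 30 of 34, with Psmb2 at 42.7 ± 4.61 against 35.7 ± 2.84 CPM (median 0.10, adjusted p = 3.21e-04, and adjusted p = 0.528 with an estimated correlation). Ribosomal protein genes were higher in 66 of 81, with Rpl7 at 0.24 ± 0.11 (median 0.07, adjusted p = 5.18e-04, and adjusted p = 0.686 with an estimated correlation). Nuclear oxidative phosphorylation genes were higher in 54 of 70, with Ndufb9 at 0.21 ± 0.08 (median 0.08, adjusted p = 5.76e-04, and adjusted p = 0.638 with an estimated correlation). Stress and unfolded protein genes were higher in 23 of 26 (median 0.13, adjusted p = 0.00481, and adjusted p = 0.638 with an estimated correlation). The chaperone Hspa5 averaged 422 ± 36.5 against 342 ± 70.2 CPM, and Calr was at 0.26 ± 0.12 log2. Immediate early genes were higher in 14 of 22 (median 0.42, adjusted p = 0.00866, and adjusted p = 0.528 with an estimated correlation), with Junb at 0.83 ± 0.36 and Ier5 at 0.54 ± 0.17. All 11 cone markers were lower, with Pde6c at 16.5 ± 12.6 against 78.6 ± 77.8 CPM and Cngb3 at -1.67 ± 0.64 log2 (median -1.89, adjusted p = 3.21e-04, and adjusted p = 0.528 with an estimated correlation). Rod markers had a median of -0.22, though the test placed the list higher than other genes, with an adjusted p of 0.831. No member of these lists passed over all genes.

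The ribosomal call at onset ended without onset 3 (adjusted p = 0.627) and turned without naive 2 (0.737), and respiration ended without naive 2 (0.104). The stress call ended without naive 4, naive 5 or onset 2 (0.116, 0.122 and 0.200) and the immediate early call without naive 4, naive 5 or onset 3 (0.0591, 0.122 and 0.128). With the length trend removed the respiration and ribosomal calls ended (0.135 and 0.0825). Without the 4 rod-rich libraries the respiration, proteasome and cone calls ended (0.0733, 0.761 and 0.633), and the stress and immediate early lists turned (0.571 and 0.633). Both also ended with the replicate number as a block (0.344 and 0.228).

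The other genes with the smallest p at onset did not pass over all genes. Adam11, a catalytically inactive ADAM protein of neurons, averaged 221 ± 12.4 CPM against 340 ± 18.0 in naive (SD, n = 4 each; edgeR adjusted p = 0.402). Ntrk2, the receptor for brain-derived neurotrophic factor, averaged 112 ± 10.7 against 150 ± 6.37, and Disp3 33.8 ± 4.95 against 52.4 ± 2.12. Psd (-0.42 ± 0.09) and Celf3 (-0.70 ± 0.15) were lower, and Rxfp3, a relaxin family receptor, was higher at 64.2 ± 9.40 against 34.6 ± 5.45. In edgeR 0 genes passed in onset against naive (888 at an unadjusted p below 0.05; smallest adjusted p 0.402). DESeq2 called 16 (10 higher and 6 lower), including all 10 of the genes with the smallest p, limma-voom 0 and edgeR with the rod index 12, of which 8 were higher.

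**Figure D4:**
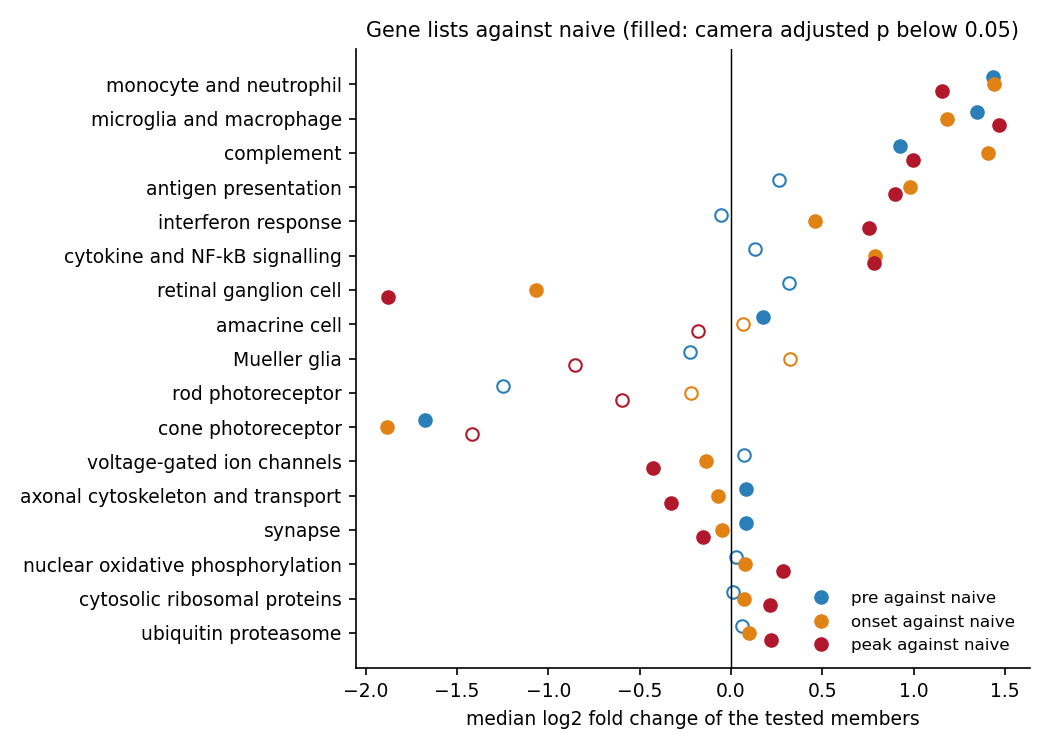
Median log2 fold change of the tested members of 17 gene lists in pre, onset and peak against naive, with filled points for lists past the camera threshold at the preset correlation. Monocyte and neutrophil markers are at 1.44 in both pre and onset, and the ganglion cell markers are at 0.32 in pre, -1.07 at onset and -1.88 in the peak library.

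From before symptoms to onset, ganglion cell and axonal genes fell as lists, and interferon, antigen presentation and cytokine genes rose as lists. The ganglion cell list was lower at onset in 12 of 14 members (median -1.17, adjusted p = 6.06e-06, and adjusted p = 0.480 with an estimated correlation). An exact permutation of its mean gave p = 0.0571 (adjusted p = 0.310). Ganglion cell subtype markers were lower in 12 of 16 (median -0.51, adjusted p = 0.0256, and adjusted p = 0.773 with an estimated correlation). Axonal genes were lower in 28 of 33 (median -0.15, adjusted p = 9.42e-07) and voltage-gated channels in 24 of 27 (median -0.18, adjusted p = 6.06e-06). Both lists had adjusted p = 0.362 with an estimated correlation, and 9 axonal and 4 channel genes passed adjusted over the list alone. Synapse genes were lower in 30 of 37 (median -0.21, adjusted p = 8.98e-06, and adjusted p = 0.483 with an estimated correlation). Glycolysis genes were lower in 16 of 22 (median -0.15, adjusted p = 2.48e-04, and adjusted p = 0.553 with an estimated correlation). Adjusted over the list alone, 1 synapse and 2 glycolysis genes passed. Heat shock genes were lower in 11 of 13 (median -0.17, adjusted p = 0.00317, and adjusted p = 0.757 with an estimated correlation). Rod markers were higher in 15 of 15 (median 0.91, adjusted p = 0.106), and microglial markers did not pass (median -0.02, 7 of 16 higher, adjusted p = 0.171). The microglial list averaged 6.55 log2 CPM in onset 3 and 4.24 to 4.53 in the other onset libraries, against 4.52 to 5.91 in pre. A median near 0 thus does not show a steady level. The subtype call ended without pre 2, pre 3 or onset 2 (adjusted p = 0.0568, 0.293 and 0.277) and the heat shock call without onset 1 (0.140).

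Interferon, antigen presentation, cytokine and immediate early genes were higher at onset than before it as lists. Complement genes (median 0.14) and monocyte and neutrophil markers (median 0.65) did not pass. Immediate early genes were higher in 17 of 22 (median 0.64, adjusted p = 8.57e-04, and adjusted p = 0.483 with an estimated correlation), and 3 passed adjusted over the list alone. Interferon genes were higher in 28 of 30 (median 0.58, adjusted p = 0.00320) and antigen presentation genes in 19 of 20 (median 0.68, adjusted p = 0.00756). Both had adjusted p = 0.773 with an estimated correlation. Cytokine and NF-kB genes were higher in 19 of 20 (median 0.66), cholesterol synthesis genes in 17 of 22 (median 0.12) and ribosomal protein genes in 61 of 81 (median 0.06), each with adjusted p = 0.0256, and adjusted p = 0.814 with an estimated correlation. The stress and unfolded protein list was higher in 18 of 26 (median 0.24, adjusted p = 0.0355, and adjusted p = 0.814 with an estimated correlation), and 1 member passed adjusted over the list alone. Without onset 3 the interferon, antigen presentation, cytokine and stress calls ended (adjusted p = 0.486, 0.633, 0.859 and 0.119) and the ribosomal list turned (0.865). Without pre 1 the antigen presentation, cytokine, stress and ribosomal calls ended (0.0998, 0.293, 0.530 and 0.351). Without pre 2 it was interferon and cytokine (0.0811 and 0.135), without pre 3 ribosomal and cholesterol (0.268 and 0.0933), and without pre 4 stress and cholesterol (0.223 and 0.596). The stress call also ended without onset 2 or naive 2 (0.356 and 0.0844), and the cholesterol call without onset 1 or onset 2 (0.0855 and 0.147). Without the 4 rod-rich libraries all 7 of these calls ended (0.0519 to 0.370), and with the length trend removed the ribosomal and stress calls did (0.231 and 0.0922). The cytokine and ribosomal calls ended with the rod index as a covariate (0.176 and 0.568).

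Single genes that differed most by p from pre to onset were Plxnb1, a semaphorin receptor, at 150 ± 19.0 against 93.9 ± 9.94 CPM (SD, n = 4 each), and Abcc8 at 13.4 ± 2.79 against 29.2 ± 6.20. Both had an edgeR adjusted p of 0.467. Ephx2 (0.66 ± 0.13), Eln, elastin (0.61 ± 0.13), Psat1, of serine synthesis (0.75 ± 0.16), and Arhgef19 (0.78 ± 0.18) were higher. Gpr26, an orphan receptor (-1.16 ± 0.24), Disp3 (-0.61 ± 0.12), Ptpn2 (-0.40 ± 0.08) and Ntrk2 (-0.38 ± 0.08) were lower. In edgeR 0 genes passed in onset against pre (1015 at an unadjusted p below 0.05), while DESeq2 called 20 (4 higher and 16 lower) and limma-voom 0.

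In the peak library, 23 genes passed as lower than in naive and 1 as higher, with the spread taken from the other groups, and 0 passed with only naive and peak in the fit. Macf1 and Dst, giant linkers of actin and microtubules, were at 656 and 718 CPM against 1532 ± 49.9 and 1570.4 ± 44.0 in naive (SD, n = 4), and Dync1h1, the dynein heavy chain of retrograde axonal transport, at 916 against 1754 ± 74.6. Pclo, a scaffold of the presynaptic active zone, was at 425 against 1014 ± 111, Kmt2a, a histone methyltransferase, at 523 against 1006 ± 49.7, and Gpr26 at 2.89 against 16.5 ± 2.84. Zbed6 (-1.24 ± 0.16), Arfgef3 (-1.22 ± 0.15) and Mdn1 (-1.02 ± 0.14) were also lower. The 1 gene that rose was Qdpr, which recycles the cofactor tetrahydrobiopterin, at 294 against 155 ± 18.4 CPM. In edgeR 24 genes passed, 1 higher and 23 lower, 7 of them by at least 2-fold, and 1424 had an unadjusted p below 0.05. Adjusted p was 0.0101 for Macf1, Dst, Zbed6 and Arfgef3, 0.0110 for Dync1h1, 0.0198 for Mdn1, 0.0338 for Pclo and Kmt2a, and 0.0449 for Gpr26 and Qdpr.

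Most of these 23 lower genes were long. Their median exon length was 16.5 kb against 4.53 kb for all tested genes, and 21 of the 23 were in the longest 10% of tested genes, while Zbed6 had 5.01 kb. Relative to the mean of the libraries, log2 expression in the peak library declined with exon length, with a slope of -0.106 per doubling, against -0.0443 to 0.0572 in the other 12 libraries. With each library's length trend removed, Zbed6 alone passed (-1.24 ± 0.16, adjusted p = 0.0401), and the median of the 23 moved from -0.92 to -0.56. The number of genes passing fell to 7 without naive 2, 6 without naive 4, 11 without pre 4, 9 without onset 1 and 10 without onset 4, and it was 0 with the replicate number as a block. Macf1, Dst, Zbed6, Arfgef3, Mdn1 and Dync1h1 passed in all 12 fits that left out 1 library, Kmt2a in 7, Pclo in 4, and Gpr26 and Qdpr in 1 each, with highest adjusted p of 0.0798, 0.0786, 0.0840 and 0.0905. DESeq2 called 293 genes (25 higher), limma-voom 99 (20 higher) and edgeR with the rod index 113 (32 higher).

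**Figure D5:**
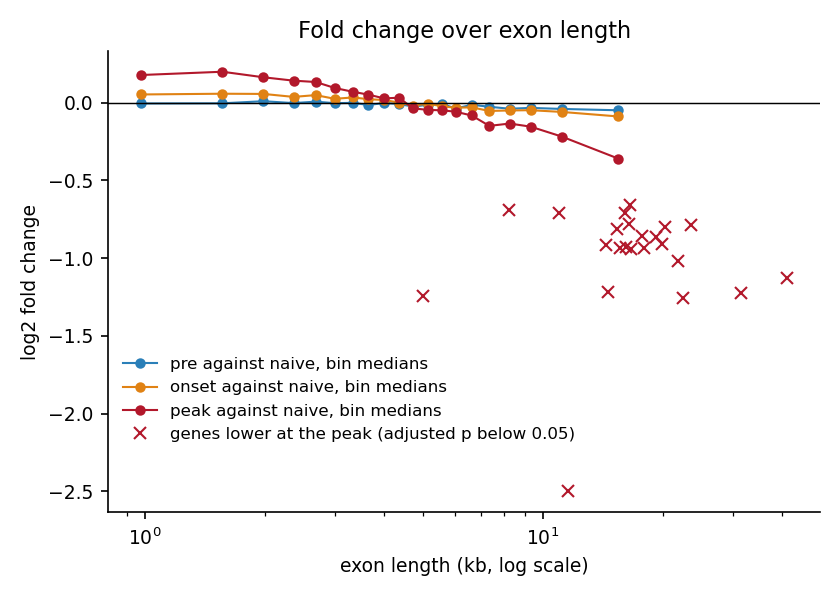
Median log2 fold change against naive in 20 bins of tested genes by exon length, for pre, onset and peak, with crosses for the 23 genes lower at the peak. In the longest bin (median 15.5 kb) the peak median is -0.36, against -0.05 in pre and -0.09 at onset.

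As a list, nuclear oxidative phosphorylation genes were higher in 69 of 70 members in the peak library (median 0.29, adjusted p = 1.48e-15, and adjusted p = 0.546 with an estimated correlation). Ndufb9, a complex I subunit, was at 66.1 against 46.9 ± 3.09 CPM (SD, n = 4) and Uqcr10, of complex III, at 44.2 against 28.7 ± 2.99. Ribosomal protein genes were higher in 75 of 81, with Rpl19 at 0.31 ± 0.11 (median 0.22, adjusted p = 1.62e-06, and adjusted p = 0.729 with an estimated correlation). Proteasome genes were higher in 31 of 34, with Psmb2 at 0.45 ± 0.15 (median 0.22, adjusted p = 3.11e-06, and adjusted p = 0.551 with an estimated correlation). Axonal genes were lower in 23 of 33, with the kinesin Kif1a at 1008 against 1561 ± 91.7 CPM (median -0.33, adjusted p = 2.29e-05, and adjusted p = 0.546 with an estimated correlation), and 1 passed over all genes and 11 adjusted over the list alone. Voltage-gated channels were lower in 23 of 27, with Cacna1c at -0.72 ± 0.18 (median -0.43, adjusted p = 1.75e-04, and adjusted p = 0.546 with an estimated correlation), and 3 passed adjusted over the list alone. Synapse genes were lower in 25 of 37, with Bsn at -0.87 ± 0.25 (median -0.16, adjusted p = 0.0130, and adjusted p = 0.616 with an estimated correlation). Pclo passed over all genes, and 3 synapse genes passed adjusted over the list alone. With the length trend removed, respiration (adjusted p = 7.75e-06), axonal (4.42e-04) and proteasome genes (0.0246) stayed past the threshold and the ribosomal (0.175), channel (0.0613) and synapse lists (0.682) did not. The synapse call also ended without naive 1 (0.0758) or naive 2 (0.0511) and with the rod index as a covariate (0.0525), and the proteasome call without the 4 rod-rich libraries (0.105).

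Immune groups were higher in the peak library as well. Antigen presentation genes were higher in 20 of 20, with the class II genes H2-Aa at 7.91 against 1.19 ± 1.16 CPM and Cd74 at 19.5 against 3.66 ± 2.53 (SD, n = 4; median 0.90, adjusted p = 9.53e-06, and adjusted p = 0.551 with an estimated correlation). Interferon genes were higher in 28 of 30, with Cxcl10 at least 17.1-fold above the naive floor (median 0.75, adjusted p = 1.62e-06, and adjusted p = 0.551 with an estimated correlation). Microglial markers were higher in 16 of 16, with C1qb at 2.06 ± 0.98 and Cd68 at 1.44 ± 0.72 log2 (median 1.47, adjusted p = 1.62e-06, and adjusted p = 0.583 with an estimated correlation). Monocyte and neutrophil markers were higher in 8 of 9 (median 1.15, adjusted p = 1.21e-04, and adjusted p = 0.551 with an estimated correlation). S100a9 was at 14.8 CPM, at least 87.7-fold higher, and S100a8 at 7.16, at least 42.4-fold, and 2 members passed adjusted over the list alone. Complement genes were higher in 12 of 14, with C5ar1 at 2.31 ± 1.03 (median 0.999, adjusted p = 0.00114, and adjusted p = 0.551 with an estimated correlation). Cytokine genes were higher in 15 of 20, with Ccl12 at 3.64 ± 0.86 log2 and Cxcl12 at 30.4 against 9.07 ± 3.55 CPM. That list had a median of 0.78 (adjusted p = 0.00223, and adjusted p = 0.616 with an estimated correlation), and 3 members passed adjusted over the list alone. Ccl2 had 3 counts in naive and 2.64 CPM at the peak. No single gene of these groups passed over all genes in edgeR.

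The mean of the ganglion cell markers was lower in the peak library, at 3.53 log2 CPM, than in any of the other 12 libraries. Onset 2 (3.71), onset 3 (3.81) and the untreated naive 1 (3.88) were close to it. In the peak library Rbpms was at 1.88 CPM against 13.1 ± 7.75 in naive (SD, n = 4), Slc17a6 at 0.754 against 17.3 ± 13.1 and Pou4f1 at 1.51 against 13.3 ± 9.20. Sncg was at 2.26 against 12.1 ± 12.3, Nefm at 34.9 against 157 ± 71.8 and Nefl at 125 against 325 ± 227. Pou4f2 had 0 counts, at least 9.27-fold lower, while Thy1 was at 655 against 480 ± 182. Naive 1 alone had Rbpms at 3.77, Slc17a6 at 1.26, Pou4f1 at 2.20 and Sncg at 1.26 CPM, though Nefm at 180. The list was lower in 11 of 14 members (median -1.88, adjusted p = 0.00642, and adjusted p = 0.583 with an estimated correlation), with no member past the threshold over all genes.

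From onset to peak, the 5 genes with the smallest p were also among those lower than in naive. Both comparisons use the same peak library, so they are not separate lines of evidence. Apart from Zbed6, these were long genes, with exon lengths of 14.6 kb (Arfgef3) to 41.2 kb (Dst). Dst was lower by -1.07 ± 0.14 log2 (adjusted p = 0.0547), Dync1h1 by -0.85 ± 0.12 and Arfgef3 by -1.02 ± 0.15 (both 0.0569), and Macf1 by -0.99 ± 0.15 and Zbed6 by -1.01 ± 0.16 (both 0.0605), all just short of the threshold. Higher, and not passing, were Vegfb, a vascular growth factor (58.2 against 39.8 ± 0.606 CPM; SD, n = 4), Lypla2 (0.40 ± 0.11), Dab2 (5.40 CPM against 3 onset counts) and the class II gene H2-Ea (22 counts against 0, at least 15.7-fold). Respiration genes were higher in 68 of 70 (median 0.21, adjusted p = 4.08e-13) and interferon genes in 23 of 30 (median 0.38, adjusted p = 0.00209), and adjusted p = 0.983 for both with an estimated correlation. Ribosomal protein genes were higher in 68 of 81 (median 0.14, adjusted p = 0.00209) and proteasome genes in 29 of 34 (median 0.14, adjusted p = 0.00485), with 0.983 for both at the estimated correlation. Axonal genes were lower in 22 of 33 (median -0.08, adjusted p = 0.00185), 6 of them adjusted over the list alone, and channels in 21 of 27 (median -0.26, adjusted p = 0.0140), again with adjusted p = 0.983 with an estimated correlation. With the length trend removed, the ribosomal (adjusted p = 0.861), proteasome (0.620) and channel (0.620) calls ended, and without onset 2 the interferon (0.137) and channel (0.146) calls did, as did the proteasome call without the 4 rod-rich libraries (0.0754) or with the replicate number as a block (0.0960). In edgeR 0 genes passed (756 at an unadjusted p below 0.05) and 9 without onset 3, DESeq2 called 113 (1 higher) and limma-voom 20 (2 higher).

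Changes from naive correlated across stages, in part because the stages share the naive libraries. Over 14893 genes, which are not independent replicates, log2 fold changes correlated at r = 0.592 for pre and onset, 0.436 for pre and peak and 0.628 for onset and peak. In 50 simulations all libraries, naive included, were drawn gene by gene around a common mean. Unchanged groups that shared their simulated naive libraries gave a mean r of 0.497, 0.333 and 0.331. The real covariance exceeded the simulated one by 0.0191, 0.0249 and 0.0555. Variation that genes share, such as rod content, was not simulated, so the excess cannot be told apart from it. The share of genes with the same sign was below the simulated one for pre and onset (64.7% against 66.6%) and for pre and peak (58.5% against 60.9%), and above it for onset and peak (70.6% against 60.8%). When the naive libraries were split into pairs, so that each stage had its own, r ran from -0.219 to 0.321 for pre and onset, -0.210 to 0.292 for pre and peak and -0.142 to 0.424 for onset and peak, with both signs present in each case. Called genes could not overlap, since 0 passed in edgeR in pre or onset (832 and 888 at an unadjusted p below 0.05).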

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

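The tests of explanations in this part were chosen after the result was seen, except the thinning of the peak library; the tests of gene lists were planned. In groups of 4 libraries, 552 sets of values were searched for a library far from its group, by the gap to its nearest neighbour over the whole range (Dixon's test). Such a library was found in 45, where chance marks about 1 in 20 groups, or 27.6 here.

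Onset 3 accounted for many of these. It stood far above the other 3 onset libraries in microglial, myeloid and immune genes: C1qa 219 CPM, C1qb 182, C1qc 192, Csf1r 433, Tmem119 62.0, Itgam 95.4, Csf3r 48.5, C5ar1 4.95, Lyz2 42.0, Cd68 37.3, Fcer1g 24.5, Ccl12 18.8, Il1b 18.5, Cxcl10 2.87, Nfkbia 54.2 and the ribosomal gene Rpl11 59.9. Its mean log2 CPM was also apart for the microglia and macrophage markers (6.55) and the bipolar cell markers (4.69). It stood far below the others in Tubb3 (28.4 CPM), Dst (1295) and Kmt2a (748).

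Elsewhere at onset, Rbpms was high in onset 1 (14.4 CPM), Cd59a low in onset 1 (6.07) and Thy1 high in onset 2 (681). Among the pre libraries, pre 3 was high in Pou4f2 (19.2), Map1a (585), Sptbn1 (1087) and Cxcl10 (0.349) and low in the oxidative phosphorylation list (mean 5.45 log2 CPM). The library pre 4 was high in Opn1mw (34.5), Ldha (532), Shank2 (311), Rps16 (57.6) and Bsn (929), pre 1 high in Rpl7 (87.9) and pre 2 low in Kcnab2 (293). In naive, naive 5 was high in Ccl12 (1.52) and Cxcr2 (0.152, a single count) and low in Shank1 (439.5), naive 2 high in Hspa5 (447) and Arhgef19 (43.3), and naive 4 high in Chil3 (0.240, a single count). Naive 1 was high in Psmb7 (56.3) and the cholesterol synthesis list (mean 6.57 log2 CPM) and low in the ganglion cell subtype list (1.88).

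The changes from naive differed between pre and onset for 14 gene lists, tested directly as onset against pre with the preset correlation. Median log2 differences were -1.17 for ganglion cell, -0.51 for ganglion cell subtype, -0.21 for synapse, -0.18 for voltage-gated channel, -0.15 for axonal, -0.15 for glycolysis and -0.17 for heat shock genes. They were 0.58 for interferon, 0.68 for antigen presentation, 0.66 for cytokine, 0.64 for immediate early, 0.24 for stress and unfolded protein, 0.12 for cholesterol and 0.0617 for ribosomal protein genes. With an estimated correlation none of the 14 passed.

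Transcripts of chosen neutrophil genes were present in all 9 EAE libraries and nearly missing from the naive ones. Csf3r, of the planned monocyte and neutrophil list and not among these genes, had 6 to 71 counts per naive library. Its means were 6.92, 23.8, 18.5 and 16.1 CPM in naive, pre, onset and peak, beside 68.3, 196, 180 and 196 for Csf1r. Over 19 neutrophil genes, listed after most had been seen, the EAE libraries held 34 to 450 counts each (8.24 to 117 CPM) and the 4 naive libraries 13 together (upper 95% Poisson limit 22.2). Lower depth of the naive libraries is argued against by their gene totals, 3308627 to 6590972 counts against 2596705 to 7641214 in the EAE libraries. At the lowest EAE rate of these genes 146 counts would be expected in naive. At the lowest EAE ratio of these counts to Csf1r, the naive Csf1r counts would bring 111. More, otherwise unchanged microglia in the EAE libraries cannot be judged from this, since genes listed after being seen can fall short by choice. The ratio to Csf1r was also taken as constant, so microglia or macrophages that changed their expression of these genes in EAE cannot be excluded as a source. Neutrophils left in blood vessels (blood left in the tissue) cannot be told apart from neutrophils in the eye, because haemoglobin genes had 0 counts in all 13 libraries, naive included, which removal of these transcripts before or during processing would also give. Entry of neutrophils with the disease stays open as a hypothesis, which may account for the signal; 3 of the 19 genes stand in the monocyte and neutrophil list.

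The 23 genes that were lower in the peak library, most of them long, had a median log2 fold change of -0.92 (median SE 0.138). With each library's length trend removed the median was -0.56 (median SE 0.119) and 1 of the 23 still passed. Smaller folds were not the only reason, since Gpr26 went only from -2.50 to -2.29 and also stopped passing. The remaining median was more than 2 SEs, but the 23 were picked for being low, which by itself leaves a remainder. Gene length bias of the peak library thus cannot be told apart from lower levels of these genes. Greater depth of the peak library is argued against, as thinning it to the mean naive total left -0.91 (median SE 0.138) and 19 genes. The disease stage at the peak stays open and cannot be told apart from this library, since 1 peak library was in the table.

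Ganglion cell markers were lower at onset than before it (median log2 difference -1.17 over 14 markers, 12 lower). Removing the length trend left -1.18 (SE 0.265) and the rod index as a covariate left -1.49 (SE 0.269). Neither gene length bias nor photoreceptor carry-over, as corrected here, thus made up the drop in this median. These SEs are over the 14 markers, which vary together, and not over libraries. They cannot show that the drop exceeds the spread between libraries. A smaller share of ganglion cells among the cells collected would move the markers of the other cells alike, and the widest gap among 15 pairs of their shifts was 2.18 SEs, beyond the bound of 2. That bound ignored that the widest of 15 pairs was taken, and 14 of the 35 splits of the 8 libraries gave a gap as wide (highest other 5.80), so this cannot be told apart from loss of these transcripts within the cells. The shifts were -0.11 ± 0.15 (SE) for amacrine, 0.28 ± 0.87 for Müller glia, 0.67 ± 0.95 for rod, -0.32 ± 0.65 for microglial, 0.45 ± 0.67 for endothelial and -0.39 ± 0.56 for bipolar markers, and a change with the disease stage stays open.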

How the results depend on the processing

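Chosen after the results were seen were the removal of the length trend, the fits without the 4 libraries richest in rod transcripts (naive 4, naive 5, pre 4 and onset 3) or without the peak library, and the permutation of list means; the other alternatives were planned. Over all settings, the named genes kept direction and side of the threshold in 4495 gene and setting pairs, lost it in 67 (10 genes), gained it in 102 (48 genes) and turned in 14 (7 genes). Most named genes had not passed to begin with. Those that had, all in peak against naive, each lost the threshold with only the 2 groups compared and with the replicate number as a block. No scaling moved the median of all genes by over 0.1 log2. The depth limits genes under 0.377 to 1.14 CPM per library. Small changes were mostly missed: of genes changed 1.5-fold in simulated data the edgeR test found 16.4%, 22.4% and 1.49% in pre, onset and peak against naive. Whether depth, spread or the number of libraries set this was not tested. Leaving out the peak library gives no value for the peak.

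Counts of genes past the threshold moved as follows. DESeq2 called 6 in pre against naive, 16 in onset against naive, 293 in peak against naive, 20 in onset against pre and 113 in peak against onset, against 0, 0, 24, 0 and 0 with edgeR (832, 888, 1424, 1015 and 756 at an unadjusted p below 0.05). The rod index as a covariate gave 99, 12 and 113 against naive and 11 in peak against onset, and limma-voom 99 in peak against naive and 20 in peak against onset. In peak against naive, 0 genes passed with only the 2 groups compared, where fewer samples set the spread, 1 with the length trend removed and 140 without the 4 rod-rich libraries. In peak against onset, 6 passed with RLE factors, 1 with no filter, 6 with a filter of 1 CPM in 4 libraries and 1 without the rod-rich libraries. Treating the replicate number as a replicate block gave 0 in all 5 comparisons; libraries of 1 number correlated at -0.393 to 0.289 (median 0.0810; 0.188 to 0.289 for the 3 pairs of naive and pre) and others at a median of -0.0593 (highest 0.484), and 1 of 12 libraries was closest to one of its own number, so the numbers were not taken as pairs. Leaving out 1 library gave 0 to 0 genes in pre against naive and in onset against pre, 0 to 1 in onset against naive (1 without onset 2), 6 to 25 in peak against naive (7 without naive 2, 6 without naive 4, 11 without pre 4, 9 without onset 1 and 10 without onset 4) and 0 to 9 in peak against onset (9 without onset 3). Apart from the cases explained, the cause was not tested.

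The list calls rest on the preset correlation, since the estimate allows for members that vary together. With an estimated correlation the adjusted p was 0.555 for microglia and for monocyte and neutrophil markers in pre against naive, 0.528 for these and for antigen presentation and ganglion cell markers in onset against naive, 0.546 for oxidative phosphorylation and axonal genes in peak against naive and 0.480 for ganglion cell markers in onset against pre. With fry it was 0.553 for both pre lists, 0.531 for microglia, antigen presentation and ganglion cell and 0.218 for monocyte and neutrophil markers at onset, 0.172 and 0.132 for oxidative phosphorylation and axonal genes at the peak and 0.277 for ganglion cell markers in onset against pre. Exact permutation of list means cannot give a p below 0.0286 with 4 against 4, the value of monocyte and neutrophil markers in both pre and onset, so over 38 lists the adjusted values say little; they were 0.494 for microglia and 0.362 for monocyte and neutrophil markers in pre, 0.679 for microglia, antigen presentation and ganglion cell and 0.362 for monocyte and neutrophil markers at onset, and 0.310 for ganglion cell markers in onset against pre. Over the libraries left out, adjusted p ran from 4.65e-19 to 5.13e-06 (microglia, pre), 6.75e-09 to 5.89e-04 (monocyte and neutrophil, pre), 2.05e-13 to 4.22e-04 (microglia, onset), 1.12e-12 to 2.28e-05 (monocyte and neutrophil, onset), 5.50e-11 to 0.00998 (antigen presentation, onset), 1.42e-04 to 0.0687 (ganglion cell, onset, lost without naive 2), 7.83e-17 to 4.92e-13 (oxidative phosphorylation, peak), 3.50e-06 to 7.93e-04 (axonal, peak) and 5.79e-09 to 2.91e-04 (ganglion cell, onset against pre). Without the rod-rich libraries the ganglion cell list at onset had 0.0733.

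Reversed directions, whose cause was not tested, came mostly without the 4 rod-rich libraries. These were, in pre against naive, Thy1 (-0.10 log2), Sncg (-0.0043), Nefl (0.75), Pde6c (0.0675), C1ql2 (-0.0173) and Tubb2a (-0.0075) and the cone (adjusted p = 0.535), amacrine (0.785) and glycolysis (0.894) lists, and in onset against naive Thy1 (-0.0686) and the stress (0.571) and immediate early (0.633) lists. In pre against naive Nefl also turned with the replicate block (0.37) and the rod index (0.15). Leaving out 1 library gave ranges of -0.0149 to 1.57 for Pou4f2 (turned without pre 3), -0.20 to 0.98 for Sncg (without naive 1, and -0.09 without naive 4 and -0.13 without pre 3) and -0.49 to 0.32 for Nefl (without naive 5). For ribosomal genes, adjusted p ranged from 1.06e-08 to 0.737 in onset against naive (turned without naive 2) and 2.98e-06 to 0.865 in onset against pre (turned without onset 3).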

Other observations

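The tests in this part were planned, and the reading of the splits by rod index was chosen after their counts were seen. Several groups with a bearing on neuronal survival showed no passing change. DNA methylation and reprogramming factors were lower than naive in 13 of 19 members in pre (median log2 -0.15, adjusted p = 0.0922), 12 of 19 at onset (median -0.09, adjusted p = 0.149) and 14 of 19 at the peak (median -0.21, adjusted p = 0.163; 1 member passed adjusted over the list alone). Apoptosis and p53 target genes were split, with 11 of 22 higher in pre (median 0.01, adjusted p = 0.843), 15 at onset (median 0.09, adjusted p = 0.314) and 14 at the peak (median 0.10, adjusted p = 0.473). Axon injury and regeneration genes were higher in 12 of 21 in pre (median 0.05, adjusted p = 0.997), though their mean was just below 0, and lower in 13 of 21 at onset (median -0.11, adjusted p = 0.194) and at the peak (median -0.12, adjusted p = 0.404). Senescence genes had 6 tested members and medians of 0.12, 0.01 and -0.22 (adjusted p = 0.997, 0.739 and 0.923).

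Other lists did not pass. T cell markers were lower in 6 of 7 in pre against naive (median -2.02, adjusted p = 0.0690) and higher in 7 of 7 from pre to onset (median 2.02, adjusted p = 0.105). These medians rested on few libraries, with mean log2 CPM of 2.53 in naive 1, 2.26 in naive 2 and 2.90 in onset 1, against 0.400 to 1.29 in the other naive, pre and onset libraries. Endothelial and pericyte markers were lower in 7 of 8 in pre (median -0.66, adjusted p = 0.0595; 1 passed adjusted over the list alone) and higher in 8 of 8 from pre to onset (median 0.68, adjusted p = 0.0718). Acute phase and reactive glia genes were higher in 15 of 19 at onset (median 0.36, adjusted p = 0.0966; 1 passed adjusted over the list alone), and oxidative stress defence genes in 19 of 24 (median 0.13, adjusted p = 0.0697). Cell cycle genes were higher in 6 of 12 at onset (median 0.01, adjusted p = 0.109), and 2 passed adjusted over the list alone. Red blood cell markers had 0 tested members, and 0 mitochondrially encoded genes were in the table.

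Other splits of the same 8 libraries into 4 and 4 were tested in the same way, 35 splits per comparison with the real one included. The real splits of pre and naive, onset and naive, and onset and pre gave 0 genes with edgeR (DESeq2 called 6, 16 and 20), which all 35 splits match by definition, so these counts decide nothing (highest other 3, 108 and 211). For the other counts chance cannot be excluded. The real split of pre and naive gave 832 genes at an unadjusted p below 0.05 (13 splits as many, highest other 2064) and 9 lists (20 splits, highest other 18). For onset and naive it gave 888 at an unadjusted p below 0.05 (14 splits, highest other 2521) and 16 lists (8 splits, highest other 24). For onset and pre it gave 1015 at an unadjusted p below 0.05 (6 splits, highest other 1721) and 14 lists (15 splits, highest other 23). In each comparison 2 of the other splits called any gene. The split with 211 genes (pre 1, pre 2, onset 2 and onset 4 against the rest) parted the 4 lowest rod indices (4.27 to 5.22) from the 4 highest (5.35 to 8.07). The split by rod index also gave the highest count at an unadjusted p below 0.05 in all 3 comparisons (2064, 2521 and 1721), so rod content is a structure of the samples besides the stage. With the rod index as a covariate, edgeR called 99, 12 and 0 genes in pre against naive, onset against naive and onset against pre. The split with 108 genes (naive 1, naive 2, onset 2 and onset 3 against the rest) did not follow the rod index, at 3.79 in naive 1 and 8.07 in onset 3. It may point to a further structure, which was not tested.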
